A study of Glycine max with 16 samples.

How the data were processed

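Small RNA libraries were made from 16 samples, 2 biological replicates of each of 8 seed subregions, with 250 ng of total RNA, an adapter ligation kit, 15 PCR cycles and a gel selection of 147 to 160 bp, per the labels' protocols. For each library the authors deposited a table of counts, with each distinct sequence of 18 to 26 nt and the number of reads that carried it. The values were whole numbers with different totals in each library, so they were treated as raw counts. Bowtie is named without a version in the submitters' processing notes, and its settings, the genome build and any filter before deposit are not given in the sources used here. The tables of 6 libraries (embryo proper 1, embryo axis 1, both endosperm and both inner integument libraries) had a header line and another line ending, and were otherwise read in the same way. No genome was used here, so sequences were neither mapped nor assigned to loci. A microRNA was counted as its exact mature sequence, which several loci can produce. The annotation of assembly Glycine_max_v4.0 lists 20 loci for miR166, 28 for miR156, 16 for miR319 and 12 for miR167.

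Total counts ran from 2995199 to 18031416 per library, and distinct sequences from 296392 to 3005649. A level of 0 counts was bounded by 3 counts, which corresponded to between 0.166 and 1.002 CPM, counts scaled to the library total. Intervals of 95% for the share of 1 library were computed by Wilson's method. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group was at 0 in a whole subregion, a fold change was given as a lower bound with 3 counts set over that subregion's libraries together. Replicates were compared over 500 abundant sequences. Their chi-square per degree of freedom was 65.4 to 768, so no pair of libraries agreed within sampling noise and none was merged.

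The choices in this paragraph were made before the data were examined. Sequences at 10 CPM or more in at least 2 libraries were tested (11836 sequences, which held 32.5 to 66.4% of the counts of a library). Counts were fitted in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood test with 1 mean per subregion over all 16 libraries and TMM normalization (factors 0.639 to 1.97). Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. There were 8 comparisons, each a contrast of subregion means on the log scale. They were embryo (embryo proper, axis and cotyledon) against seed coat (epidermis, hilum, inner and outer integument), endosperm against embryo, endosperm against seed coat, axis against cotyledon, and each seed coat subregion against the other 3. The p-values measure a contrast against the spread between replicates within subregions, not against the spread between the subregions of a compartment. A mean on the log scale can order 2 groups differently from a mean of CPM. Means of CPM over several subregions are means of subregion means.

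Of microRNAs, 6 lists with 50 members were fixed. They were development (21 members, 16 tested), nutrient (copper and other nutrients and stress, 7 members, 4 tested), machinery (regulators of small RNA genes, 4 members, 2 tested), nlr (microRNAs of disease resistance genes, 7 members, 4 tested), legume (9 members, 4 tested) and tasiARF (2 members, 0 tested). The 20 members under the filter, among them both tasiARF sequences, miR165, miR172 and miR403, are not analysed here. A list was tested with fry (limma 3.58.1), which asks whether the members moved on balance in 1 direction and does not compare them with other sequences. Its p-values were adjusted over the 40 tests of 5 lists in 8 comparisons. Of these, fry called 25, and camera with an estimated correlation between sequences called 0 (lowest adjusted p = 0.346). At an unadjusted p under 0.05 camera had 5. Camera asks another question than fry, whether the members moved more than the other tested sequences. It is therefore not the fry test repeated with a correlation, and the calls need not match. Shares of 21-nt and 24-nt counts were compared by exact two-sided permutation tests of the difference of means, over 35 splits of 7 subregion means for embryo against seed coat and 120 splits of 16 libraries for endosperm against the rest. The smallest p these can give is 0.0286 and 0.00833.

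Named were the list members past the threshold, at most the 12 largest log2 fold changes per direction in the 4 comparisons between or within compartments and at most 4 in the 4 seed coat comparisons. Outside the lists, the 2 sequences per direction with the lowest p were named, if their mean reached 100 CPM on the higher side. A member beyond this rule was named only where a list count of 5 or fewer rested on it, and was chosen after its values were seen. A sequence that holds bases 2 to 17 of a list member is called an end variant of it, since it can differ in length and in its outer bases, without regard to its locus. Other sequences outside the lists were not checked for complementarity to list members or a shared precursor. They need not be findings independent of these members.

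The fit was tested on simulated counts of the 11836 sequences, of which 60 were changed by 2-fold, 70 by 4-fold and 70 by 16-fold. For embryo against seed coat it recovered 2, 59 and 70 of these, with 7 false calls among 138. For endosperm against embryo it recovered 2, 30 and 59, with 5 false calls among 96. For axis against cotyledon it recovered 0, 9 and 49, with 4 false calls among 62. All other sequences had the same simulated level in every subregion, and the changes went in random directions. The simulation therefore does not test the scaling where many real sequences differ.

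Alternatives were library totals without TMM, DESeq2 1.42.0 with its own size factors, only 20 to 22 nt sequences, a filter of 1 CPM (220070 sequences), the replicate number as a term, each library left out in turn, embryo as axis and cotyledon only, the sum of end variants, camera in place of fry, and, for shares, distinct sequences or the removal of the 20 most abundant sequences of each library. Fits without the hilum libraries, without the inner integument libraries, and without sequences whose first 6 bases were depleted in the hilum were added after the data were seen, as was the test of endosperm shares over 8 subregion means, whose smallest p is 0.125. Lists were not tested under DESeq2. Chalcone synthase small RNAs, 24-nt windows of the genome and annotated ribosomal, transfer and plastid RNA classes are not analysed here. Fragments of the end of 5S ribosomal RNA were counted as sequences contained in CTGGGAAGTCCTCGTGTTGCACCTCT. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.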

Results

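Small RNAs of 18 to 26 nt were counted in 8 dissected parts of soybean (Glycine max, cultivar Williams 82) seeds at the cotyledon stage, from seeds of 3.0 to 3.5 mm. The embryo was sampled as embryo proper, axis and cotyledon, and the seed coat, the maternal tissue around it, as epidermis, hilum (the attachment scar), inner integument and outer integument. The endosperm, the nutritive tissue, was sampled on its own. The titles name axis and cotyledon as parts of the embryo proper, but the labels do not say whether the embryo proper samples were the whole of it. Each subregion had 2 biological replicates. The total count ranged from 2995199 in embryo axis 1 to 18031416 in epidermis 1. Replicates correlated across the 11836 tested sequences, which are not independent, with Pearson's r between 0.868 in the endosperm and 0.949 in the outer integument.

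The first question was how the size classes of small RNA, which different Dicer enzymes produce, were divided among the parts of the seed. The 24-nt class, the usual size of siRNAs of silent chromatin, held 56.3% ± 2.06 (SD, n = 2) of counts in the hilum and 52.9% ± 2.46 in the outer integument, but 24.1% ± 1.26 in the inner integument. The inner integument had the largest mean 22-nt share, 21.2% ± 2.07, against means of 6.81 to 13.6% in the other subregions. Part of it was GAAGTCCTCGTGTTGCACCTCT, a 22-nt fragment of 5S ribosomal RNA, at 50939 ± 13830 CPM (n = 2). The 21-nt class, the usual size of microRNAs, held 39.1% ± 4.10 in the axis, 37.0% ± 1.14 in the epidermis and 11.6% ± 0.52 in the hilum. In the endosperm it held 15.3% ± 0.32. A large part of this class was miR166, at 255643 CPM in the axis and 298764 CPM in the epidermis. In the hilum libraries miR166 was at 30.95 and 24.25 CPM, which may be a loss by first bases, described below. The 21-nt and 24-nt shares of the hilum may therefore not reflect the tissue alone. Reads of 18 to 20 and 25 to 26 nt made up 29.3% ± 5.80 in the endosperm and 31.2% ± 3.32 in the inner integument, against means of 9.19 to 13.8% elsewhere. Fragments of the end of 5S ribosomal RNA made up 18.8% ± 1.01 in the inner integument and 6.76% ± 3.59 in the endosperm, against means of 1.92 to 4.28% elsewhere.

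Between embryo and seed coat, the 21-nt share differed by 10.3 points (31.0% against 20.7%, exact permutation p = 0.2) and the 24-nt share by 0.1 points (43.5% against 43.4%, exact permutation p = 1.0). The endosperm differed from the other 14 libraries by -9.85 points at 21 nt (exact permutation p = 0.225) and -8.5 points at 24 nt (exact permutation p = 0.3). None of these passed after adjustment over the 4 tests (adjusted p 0.4 to 1.0 in the permutation tests). The 21-nt difference between embryo and seed coat reversed without the 20 most abundant sequences of each library (6.11% against 8.57%, exact permutation p = 0.143). Among distinct sequences it reversed too (4.1% against 6.12%, exact permutation p = 0.143). Without the 20 most abundant sequences of each library, the 21-nt share of the endosperm was instead the higher one, 12.9% against 7.52% (exact permutation p = 0.00833 over libraries, the smallest possible). The 24-nt share was then 38.3% against 59.7% (exact permutation p = 0.0417), and among distinct sequences the differences were 4.24 and -15.02 points (exact permutation p = 0.025 and 0.0333). These p-values treat the 2 libraries of a subregion as independent. Over 8 subregion means, a test chosen after these values were seen, the permutation p was 0.125 for both differences at 21 nt, the smallest possible, and 0.25 for both at 24 nt. Among distinct sequences the inner integument, counted with the rest, was close to the endosperm. Its shares were 9.07% at 21 nt and 48.63% at 24 nt, against 9.49% and 50.55% in the endosperm. Means in the remaining subregions were 3.56 to 5.68% and 64.8 to 71.17%. The shift among distinct sequences was therefore not particular to the endosperm. The endosperm and inner integument libraries also held the fewest distinct sequences, 296392 to 618380, against at least 760856 in the others. Whether this bears on their shares of distinct sequences was not tested.

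**Figure D1:**
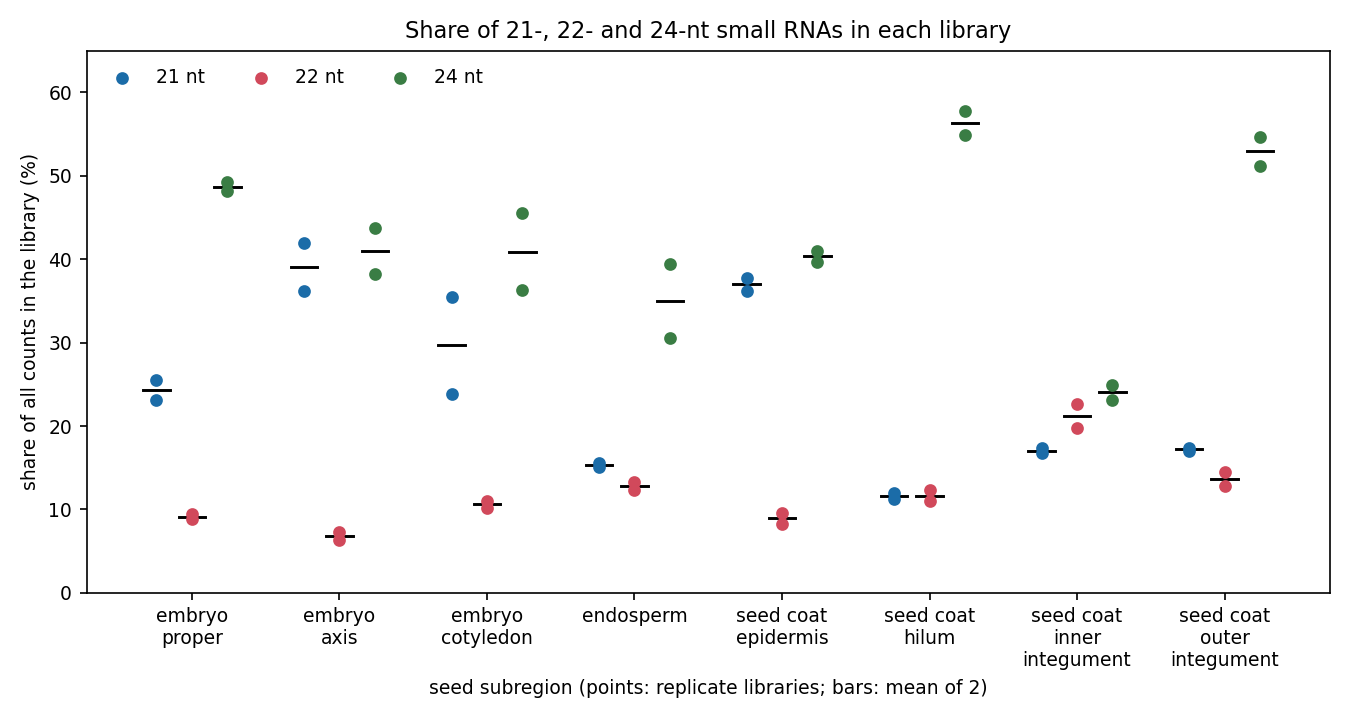
Share of all counts (%) taken by 21-, 22- and 24-nt sequences in each library, by subregion (points are the 2 replicate libraries, bars their mean). The 24-nt mean is 56.3% in the hilum and 24.1% in the inner integument, where the 22-nt mean is 21.2%. A possible loss of sequences by their first bases in the hilum libraries bears on the hilum shares.

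The embryo differed from the seed coat in many microRNAs of development, copper homeostasis and legume families. Of the 16 tested development members, 8 rose in the embryo, 5 fell and 3 did not pass, and the counts adjusted over the list alone were 8 and 5. miR156a, which represses SPL genes of phase change, rose by 7.94 on the log2 scale (SE 0.40, 3655 against 24.6 CPM). miR319a, a repressor of TCP genes, rose by 6.63 (SE 0.42, 622 against 7.55 CPM), and miR319b was at least 348-fold higher. miR160, which targets auxin response factors, rose by 3.51 (SE 0.42) and miR171a by 1.70 (SE 0.49). Lower in the embryo were miR396b (-7.94, SE 0.56, 1.66 against 698 CPM) and miR396a (-4.27, SE 0.51), which repress growth-regulating factors, as well as miR164 (-4.09, SE 0.35), a repressor of NAC genes of organ boundaries. miR394, whose target encodes an F-box protein of stem cell signalling, was lower by -4.02 (SE 0.53), and miR156b was at least 34.4-fold lower. In the nutrient list 3 members rose and 1 fell, with the same counts over the list alone. They were miR398b (6.08, SE 0.32, 12303 against 757 CPM), which represses copper/zinc superoxide dismutases, miR397 (4.12, SE 0.54), which represses laccases, miR408 (2.58, SE 0.30), a repressor of blue copper proteins, and miR2119 (-2.83, SE 0.39). In the legume list 2 of 4 rose, miR3522 (4.57, SE 0.33, 3713 against 236 CPM) and miR1511 (0.96, SE 0.31), also over the list alone. None of the 2 machinery members (1 fell when adjusted over the list alone) and none of the 4 nlr members passed, by edgeR's test.

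Outside the lists, the sequences with the lowest p that were higher in the embryo were TTGGACTGAAGGGAGCTCCCTT, an end variant of miR319 (at least 416-fold, 223 against 0.212 CPM), and TGAGACCAAATGAGCAGC, one of miR3522 (6.35, SE 0.33). Those that were lower were GAGGATGCATAACTGAAACT (at least 779-fold lower) and AGATCATGTGGCAGTTTCACC (at least 139-fold lower, 5.13 against 430 CPM). In all, 5387 of the 11836 sequences passed edgeR's test, 2839 higher and 2548 lower (2441 and 2789 without TMM, 3036 and 3166 with DESeq2), around a median log2 fold change of 0.20 over all tested sequences (0.07 without TMM). Of the higher ones 54.2% were 24 nt long, and of the lower ones 35.8%, against 49.3% of all tested.

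By fry, the development (adjusted p = 0.00576), nutrient (adjusted p = 0.000329) and legume lists (adjusted p = 0.000227) were higher in the embryo. By camera, which compares them with the other sequences, adjusted p was 0.69, 0.562 and 0.566. The machinery (adjusted p = 0.421) and nlr lists (adjusted p = 0.144) were not called. The development call was lost without epidermis 1, or without either library of the hilum, inner integument or outer integument (adjusted p 0.143 to 0.247), and without both inner integument libraries (adjusted p = 0.358). It was also lost at 1 CPM (adjusted p = 0.0596), and turned to lower with summed end variants (adjusted p = 0.0137). In that setting miR167a and miR167c, miR319a and miR319b, and miR396a and miR396b each share 1 sum, so the list holds these sums more than once. The nlr list was called lower without epidermis 1 (adjusted p = 0.0403), without TMM (adjusted p = 0.00258), at 1 CPM (adjusted p = 0.0267) and with the embryo as axis and cotyledon only (adjusted p = 0.0444). miR166, the repressor of class III homeodomain genes, stood at 4.40 (SE 0.34), at 1.46 (SE 0.36) without the hilum libraries and at 1.81 (SE 0.30) as a sum of end variants. The exact miR167a sequence, of a family that represses auxin response factors, was at least 30.6-fold higher, whereas the sum of its end variants, which takes in miR167c and other forms, was lower (-3.87, SE 0.33). For miR319a and miR319b that sum stood at 3.38 (SE 0.30). miR408 had the lower mean CPM in the embryo (1445 against 2234), and stood at 4.31 (SE 0.38) without the inner integument and 1.14 (SE 0.33) without the hilum libraries. In the same 2 settings miR398b stood at 7.43 (SE 0.42) and 5.14 (SE 0.36) and miR397 at 4.98 (SE 0.62) and 3.33 (SE 0.55), and of the 18 members named by the rule 13 and 8 moved by over 1.5-fold. As a sum of end variants miR396a stood at -7.01 (SE 0.43). The call of miR1511 was lost without embryo axis 2 (adjusted p = 0.0664), at 1 CPM (adjusted p = 0.134), without the inner integument libraries (adjusted p = 0.0654) and as a sum of end variants (-0.02, SE 0.30). With the embryo as axis and cotyledon only, the calls of miR1511 (adjusted p = 0.0614) and miR171a (adjusted p = 0.0515) were lost.

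**Figure D2:**
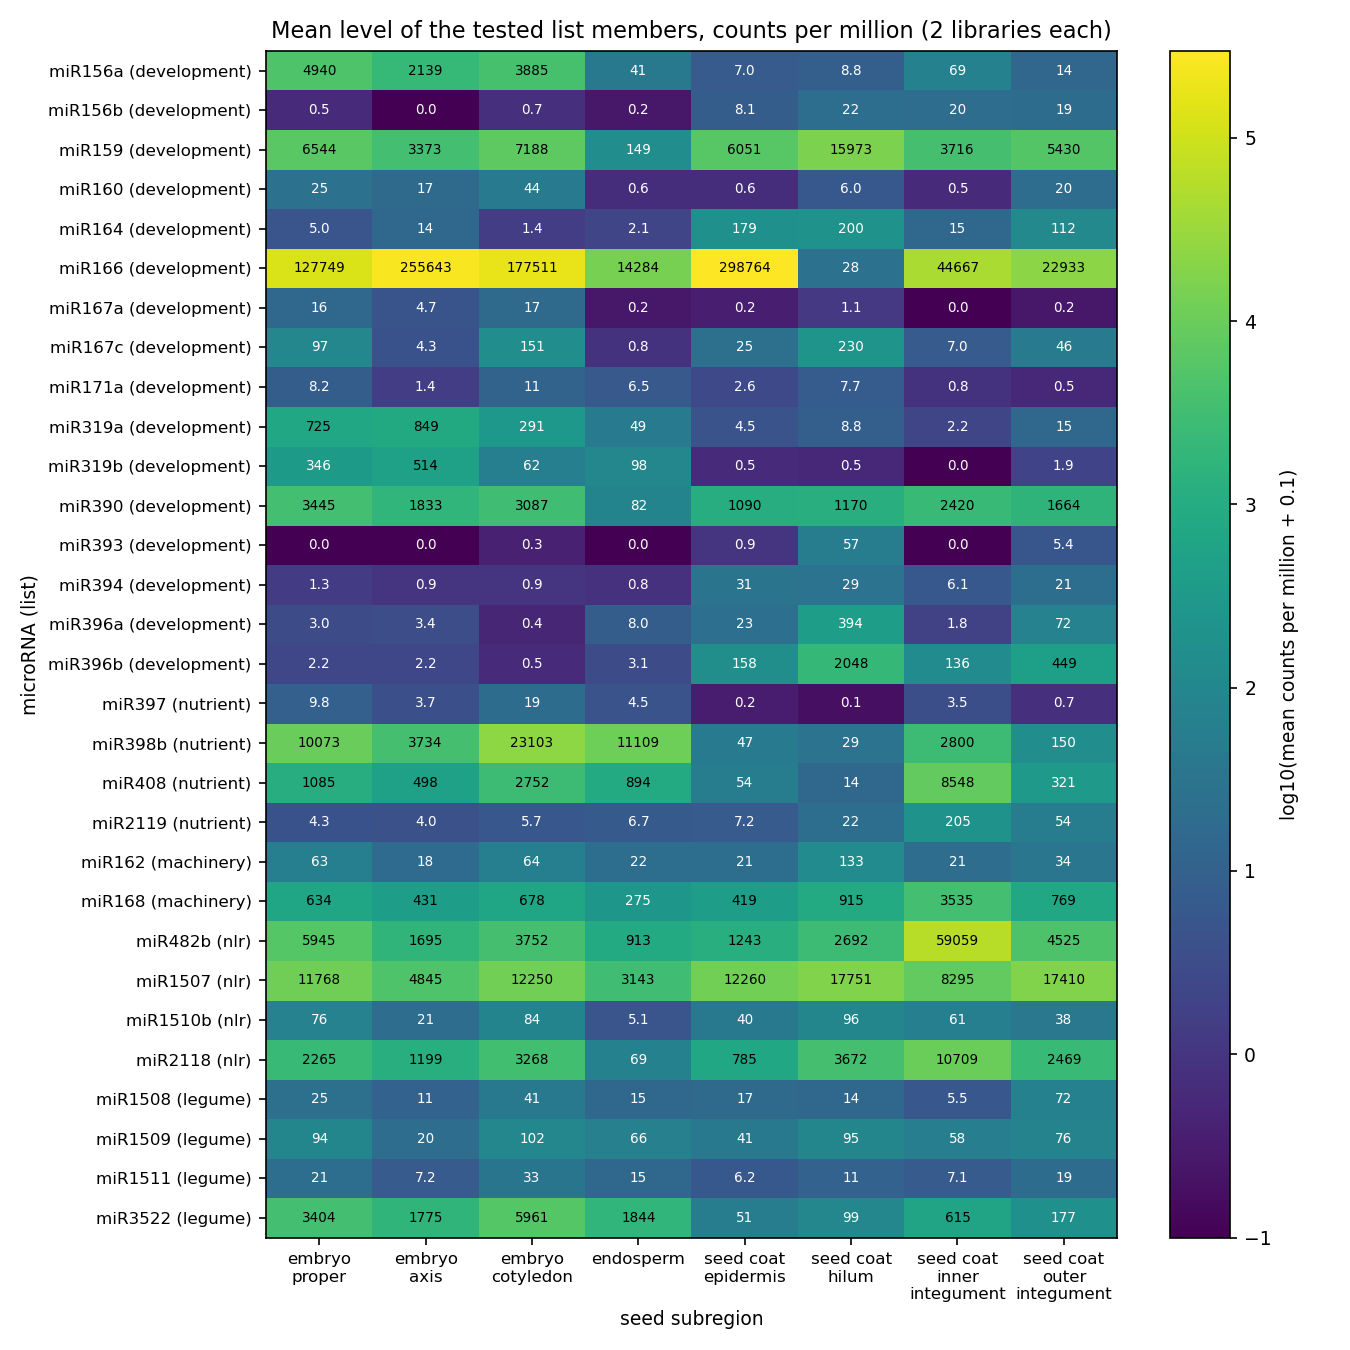
Mean CPM over 2 libraries of the 30 tested list members (vertical axis, with their list) in the 8 subregions (horizontal axis), with colour on a log10 scale after adding 0.1. miR398b is at 23103 in the cotyledon and 29.1 in the hilum, and miR482b at 59059 in the inner integument.

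The endosperm held lower levels of most tested microRNAs than the embryo. In the development list 10 members fell, 1 rose and 5 did not pass, as also over the list alone. miR156a was lower by -7.17 on the log2 scale (SE 0.74, 40.7 against 3655 CPM), miR159, which represses GAMYB genes, by -6.02 (SE 0.57, 149 against 5702 CPM), and miR390, the trigger of trans-acting siRNAs that regulate auxin response factors, by -5.78 (SE 0.66, 81.5 against 2788 CPM). miR166 was lower by -4.44 (SE 0.64, 14284 against 186968 CPM), and miR319a by -4.25 (SE 0.69). Near the detection floor in the endosperm were miR160 (-6.33, SE 0.93), miR167c (-6.46, SE 0.82) and miR167a, which had 1 count there (82.2-fold lower, 95% counting interval 14.8 to 3248). All 4 tested nlr members fell, also over the list alone: miR2118 (-5.80, SE 0.55, 69.2 against 2244 CPM), miR1510b (-4.15, SE 0.64), miR482b (-2.83, SE 0.54) and miR1507 (-2.29, SE 0.54, 3143 against 9621 CPM). Both machinery members fell, also over the list alone: miR168, which represses an Argonaute gene of the microRNA pathway (-2.02, SE 0.47), and miR162, which represses a Dicer-like gene (-1.77, SE 0.56). The legume list had 2 that fell, also over the list alone, miR3522 (-1.63, SE 0.50) and miR1508 (-1.50, SE 0.49). The nutrient list had 2 that fell, miR397 (-1.74, SE 0.77) and miR408 (-1.20, SE 0.48), and 0 over the list alone, while miR398b stood at 11109 against 12303 CPM and did not pass. miR396a rose by 1.48 (SE 0.66) at 7.95 against 2.25 CPM. The endosperm libraries were also those with 29.3% of reads of 18 to 20 and 25 to 26 nt and 6.76% of 5S ribosomal RNA fragments.

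Outside the lists, ATGTGTTTTGGGTTGTTGAGAAGT (8.00, SE 0.50) and TTCGAGGTCGAGCAGAAGCTG (6.35, SE 0.42, 1476 against 14.4 CPM) were higher in the endosperm. Lower were TGAGTTGGGTGGTAACGGGGA, with 3 counts in the endosperm (796-fold, 95% counting interval 272 to 3858), and CACCGACACATGTAGAGCCTTG (-7.45, SE 0.68, 3.24 against 345 CPM). By edgeR's test 8181 sequences changed, 3335 higher and 4846 lower, and 77.2% of the lower ones were 24 nt long against 30.6% of the higher ones. The median over all tested sequences was -0.46, and 0.00 without TMM, where the split was 4573 higher and 4012 lower. The fry test called the development (adjusted p = 0.000227), nlr (adjusted p = 9.16e-05), machinery (adjusted p = 0.00288) and legume lists (adjusted p = 0.00383) lower. By camera, against the other sequences, adjusted p was 0.562, 0.471, 0.664 and 0.69. The nutrient list was not called (adjusted p = 0.0541), although it was lower without embryo axis 2 (adjusted p = 0.0172), without endosperm 2 (adjusted p = 0.0133), with only 20 to 22 nt sequences (adjusted p = 0.00694) and with the embryo as axis and cotyledon only (adjusted p = 0.0444). The legume call was lost without endosperm 1 (adjusted p = 0.0631) and without TMM (adjusted p = 0.0894). The call of miR396a was lost in 10 of the 16 fits that left out 1 library (embryo proper 2, either axis, cotyledon 1, endosperm 2, either epidermis, hilum 1 or either inner integument, highest adjusted p = 0.169) and with only 20 to 22 nt sequences (adjusted p = 0.194). Summed end variants gave -3.71 (SE 0.55) for miR167a and miR167c, and without TMM all 13 members named by the rule moved up by over 1.5-fold, for example miR156a to -6.41 (SE 0.65), miR2118 to -4.90 (SE 0.54), miR1507 to -1.50 (SE 0.48) and miR396a to 2.29 (SE 0.65).

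Against the seed coat the endosperm also had lower levels of most development and nlr microRNAs, but higher levels of miR398b, miR3522 and the exact miR319a and miR319b sequences. In the development list 9 members fell, 2 rose and 5 did not pass, as over the list alone. miR159 (-6.18, SE 0.57, 149 against 7792 CPM), miR164 (-6.18, SE 0.66), miR167c (-6.18, SE 0.81), miR390 (-4.83, SE 0.62), miR394 (-5.42, SE 0.97), miR396b (-7.47, SE 0.91, 3.12 against 698 CPM) and miR160 (-2.82, SE 0.90) were lower. miR156b had 1 count in the endosperm (113-fold lower, 95% counting interval 20.4 to 4478), and miR160, miR167c and miR394 were near the floor there. miR319b was at least 153-fold higher and miR319a rose by 2.38 (SE 0.47, 49.3 against 7.55 CPM). All 4 nlr members fell, also over the list alone, among them miR2118 (-6.16, SE 0.56), miR1510b (-4.15, SE 0.63) and miR482b (-3.35, SE 0.55). Both machinery members fell, also over the list alone (miR168 -2.68, SE 0.49, and miR162 -1.49, SE 0.54). In the nutrient list miR398b (5.51, SE 0.35, 11109 against 757 CPM), miR397 (2.38, SE 0.73) and miR408 (1.38, SE 0.39) rose and miR2119 fell (-3.04, SE 0.64), with the same counts over the list alone. In the legume list only miR3522 of 4 rose (2.95, SE 0.38, 1844 against 236 CPM), also over the list alone.

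Outside the lists, TTCGAGGTCGAGCAGAAGCTG (8.76, SE 0.40) and CTTACAGAGAATGGAGCGCCT (8.84, SE 0.43, 5689 ± 2500 against 10.9 CPM) were higher in the endosperm. TTGGGACAATACTTTAGATAT (-8.12, SE 0.70) and TGAAGCTGCCAGCATGATCTT, an end variant of miR167 (-7.91, SE 0.69, 10.1 against 1536 CPM), were lower. Of 8341 changed sequences by edgeR's test, 3378 were higher and 4963 lower, and 70.3% of the lower ones were 24 nt long. The split was 4129 and 4138 without TMM and 26849 and 25316 at 1 CPM, and without TMM 17 of the 18 members named by the rule moved up by over 1.5-fold. The median over all tested sequences was -1.12, and -0.42 without TMM. Called lower by fry were the development (adjusted p = 0.00272), nlr (adjusted p = 8.06e-05) and machinery lists (adjusted p = 0.00208), and higher the nutrient list (adjusted p = 0.00323). By camera, against the other sequences, these had adjusted p = 0.69, 0.471, 0.664 and 0.664. The legume list was not called (adjusted p = 0.277, median -0.42, mean 0.27 and test direction higher), but was higher without TMM (adjusted p = 0.000251). The nutrient call was lost without the hilum libraries (adjusted p = 0.0626) and at 1 CPM (adjusted p = 0.0508). As a sum of end variants, miR319a and miR319b no longer passed (0.30, SE 0.41, adjusted p = 0.535). miR166 did not pass (-0.04, SE 0.47), but was lower without the hilum libraries (-2.87, SE 0.60). miR408, with the lower mean CPM in the endosperm (894 against 2234), stood at 0.04 (SE 0.46) without the hilum libraries, at 3.21 (SE 0.43) without the inner integument libraries and at 1.02 (adjusted p = 0.0589) without endosperm 2. Calls were also lost for miR397 without endosperm 2 (adjusted p = 0.0711) and for miR160 without endosperm 2 (adjusted p = 0.062), without inner integument 2 (adjusted p = 1.0) and without TMM (adjusted p = 0.0576).

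Between axis and cotyledon, the 2 separately sampled embryo parts, few microRNAs passed. In the simulation this comparison recovered 0 of 60 2-fold and 9 of 70 4-fold changes. Members that did not pass may therefore still differ. In the development list miR164 (3.85, SE 0.65, 14.2 against 1.39 CPM) and miR319b (3.57, SE 0.68, 514 against 61.7 CPM) were higher in the axis, miR167c was lower (-4.60, SE 0.72, 4.26 against 151 CPM) and 13 did not pass, whereas over the list alone 5 rose and 2 fell. In the nutrient list miR398b was lower in the axis (-2.11, SE 0.52, 3734 ± 1313 against 23103 ± 2644 CPM, n = 2) and 3 members did not pass, while over the list alone 2 fell. No machinery, nlr or legume member passed over all sequences in edgeR's test, and 4 legume members fell over the list alone (miR1511 -1.66, miR1509 -1.78, miR1508 -1.45 and miR3522 -1.23). Outside the lists, TTGGACTGAAGGGAGCTCCCTT, an end variant of miR319 (4.09, SE 0.63, 397 against 33.4 CPM), and TTCTCGGACCAGGCTTCATTCC, one of miR166 (3.65, SE 0.60), were higher in the axis, and TAGAAGCTCCCCATGTTCTCA (-2.64, SE 0.51, 104 against 920 CPM) and CTTACAGAGAATGGAGCGCCT (-3.08, SE 0.62) lower.

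In all, 100 sequences passed edgeR's test between axis and cotyledon, 29 higher and 71 lower. The split was 25 and 194 without TMM and 142 and 165 with DESeq2, and the median over all tested sequences moved from -0.05 to -0.57 without TMM. The number was 26 without axis 1 (16 higher and 10 lower), 8 without axis 2 (7 higher and 1 lower), 19 without cotyledon 1 (2 higher and 17 lower), 19 without cotyledon 2 (3 higher and 16 lower), and 152 and 155 without endosperm 1 and 2. The nutrient (adjusted p = 0.0127), nlr (adjusted p = 0.0459) and legume lists (adjusted p = 0.00323) were lower in the axis by fry. By camera, against the other sequences, adjusted p was 0.346, 0.471 and 0.346. The development (adjusted p = 0.657, median -0.30, mean -0.13 and test direction higher) and machinery lists (adjusted p = 0.17) were not called. The machinery list was called lower without TMM (adjusted p = 0.00642) and at 1 CPM (adjusted p = 0.0473). The nutrient call was lost without axis 2 (adjusted p = 0.0917), without cotyledon 1 (adjusted p = 0.0512) and at 1 CPM (adjusted p = 0.0647). The nlr call was lost in 10 fits that left out 1 library (either axis, cotyledon 1, endosperm 1, or either library of the hilum, inner or outer integument, adjusted p 0.051 to 0.19), with 20 to 22 nt sequences (adjusted p = 0.0817), with the replicate number as a block (adjusted p = 0.0545) and without the hilum (adjusted p = 0.0626) or inner integument libraries (adjusted p = 0.0737). The calls of miR164 and miR319b were lost without axis 2 or either cotyledon library (highest adjusted p = 0.145 and 0.217), and that of miR167c without either axis library (adjusted p = 0.0634 and 0.0572). miR398b lost its call in 12 of 16 such fits (any but those without embryo proper or endosperm libraries, highest adjusted p = 0.887), with 20 to 22 nt sequences (adjusted p = 0.0696), at 1 CPM (adjusted p = 0.0533) and without the hilum (adjusted p = 0.0676) or inner integument libraries (adjusted p = 0.0836). The 4 sequences outside the lists each lost their call without 1 or more of the 4 axis and cotyledon libraries, with highest adjusted p of 0.0663, 0.126, 0.445 and 0.452.

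The hilum was compared with the other seed coat subregions. In its development list 6 members rose, 2 fell and 8 did not pass, and over the list alone 8 rose and 2 fell. Among those that rose were miR396b (2.69, SE 0.51, 2048 ± 372 CPM, n = 2, against 248), miR396a (4.17, SE 0.54, 394 against 32.2 CPM) and miR393, which represses auxin receptor genes (at least 46.0-fold higher, 56.9 against 2.10 CPM). miR167c rose by 2.96 (SE 0.45, 230 against 25.9 CPM). miR166 was lower by -11.79 (SE 0.90), at 27.6 ± 4.74 CPM (n = 2) against 122121. In the nutrient list miR408 (-5.81, SE 0.64, 14.1 against 2974 CPM) and miR398b (-3.80, SE 0.53) fell and 2 did not pass, while over the list alone all 4 fell. In the nlr list miR482b fell (-1.96, SE 0.51), in the machinery list miR162 rose (1.81, SE 0.46) and in the legume list miR3522 fell (-1.47, SE 0.49), each 1 also over the list alone.

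A form of miR166 with 1 more T at its 5′ end, TTCGGACCAGGCTTCATTCCCC, was at 11283 ± 1203 CPM (n = 2) in the hilum, within the 279 to 21712 CPM of the other 14 libraries. Distinct sequences that started TCGGAC and were not miR166 stood at 32.9 and 33.7 in the hilum libraries, on the CPM scale relative to all distinct sequences, against 245.8 to 389.9 in the others. In both hilum libraries 31 of 3135 starts of 6 bases were depleted at least 5-fold, and 87 tested sequences (0.735%) began with one of them. Of the named items these were miR166 and 2 of its shorter forms.

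**Figure D3:**
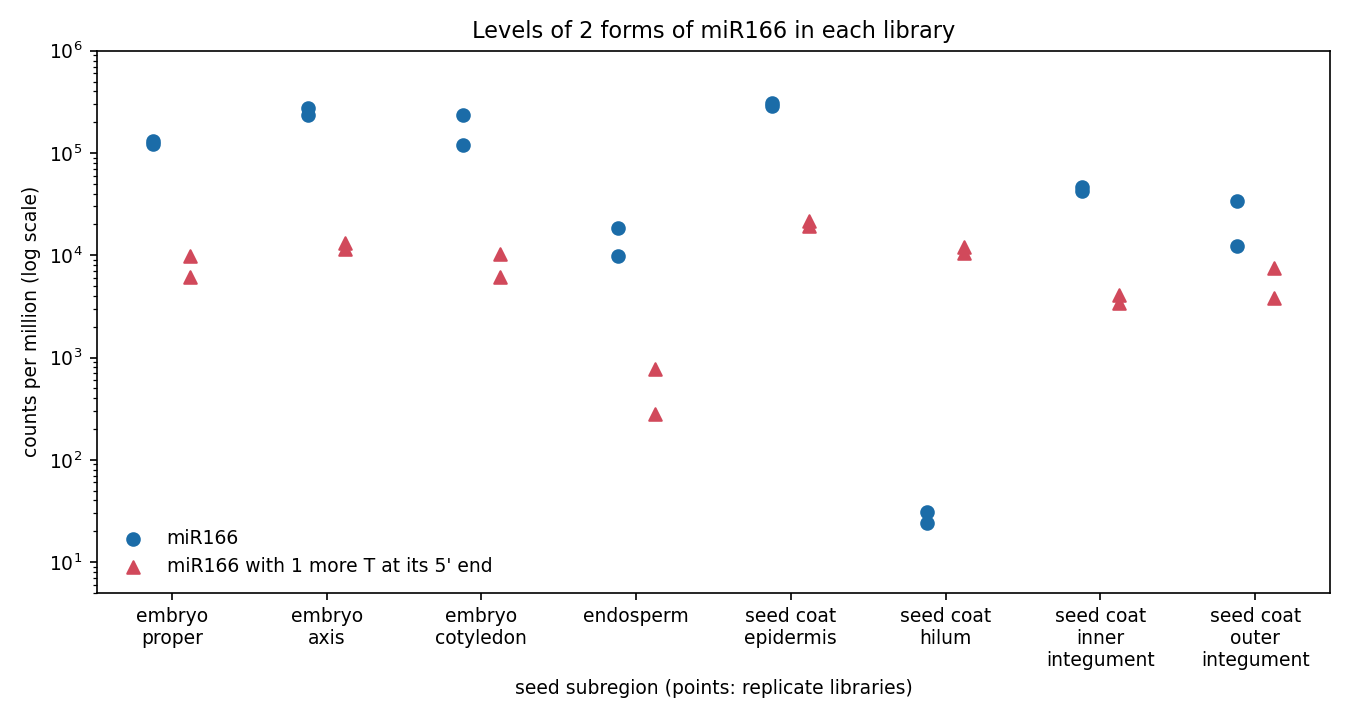
CPM (log axis) of miR166 and of its form with 1 more T at the 5′ end in each library, by subregion (points are replicate libraries). In the hilum miR166 has a mean of 27.6 CPM and the longer form one of 11283.

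Outside the lists, TTCTCGGACCAGGCTTCATTCC, another end variant of miR166 (at least 512-fold), and CACCGACACATGTAGAGCCTTG (5.50, SE 0.41, 152 against 2.68 CPM) were higher in the hilum, and TTCACGTCGGGTTCACCA (-12.47, SE 0.82, 0.569 against 2587 CPM) and TGTGGCTGGATGGAATCC (-10.54, SE 0.75, 0.484 against 505 CPM) lower. These lower 2 were at no less than 358 and 161 CPM in every other subregion. Past their first bases they hold TCGGGT and GGATGG, which are among the starts depleted in the hilum. Whether a loss in the hilum libraries reached them was not tested. TCGGAC from base 2 of a sequence was not scarce there (252.6 and 299.3, against 248.6 to 367.0 in the others, miR166 left out). By edgeR's test 2591 sequences changed, 1250 higher and 1341 lower, and 67.8% of the higher ones were 24 nt long against 34.0% of the lower ones. The split was 2601 and 910 without TMM and 2335 and 1501 with DESeq2, and the median over all tested sequences was -0.17, 0.32 without TMM and 0.03 with DESeq2. Without TMM 4 of the 8 members named by the rule moved up by over 1.5-fold. The count was 824 without hilum 1, 1099 without hilum 2 and 1308 without the inner integument libraries. By fry the development list was higher (adjusted p = 0.0352) and the nutrient list lower (adjusted p = 0.000464). By camera, against the other sequences, adjusted p was 0.566 and 0.346. The machinery (adjusted p = 0.144), nlr (adjusted p = 0.291) and legume lists (adjusted p = 0.0671) were not called. The development call was lost in 9 fits that left out 1 library (either axis, cotyledon 1, epidermis 1, hilum 1 or either library of the inner or outer integument, adjusted p 0.0518 to 0.151), at 1 CPM (adjusted p = 0.0508) and without the inner integument libraries (adjusted p = 0.488). The legume list was called lower without epidermis 1 (adjusted p = 0.00811), and the machinery list higher without outer integument 2 (adjusted p = 0.0437), without TMM (adjusted p = 0.00134), with 20 to 22 nt sequences (adjusted p = 0.00469) and with summed end variants (adjusted p = 0.0354). The call of miR482b was lost without hilum 1 (adjusted p = 0.1), without hilum 2 (adjusted p = 0.0869) and without the inner integument libraries (-0.48, SE 0.51). Summed end variants gave -0.18 (SE 0.43) for miR167c and -2.07 (SE 0.51) for miR166, and without the inner integument libraries miR396a stood at 2.59 (SE 0.60), miR167c at 2.14 (SE 0.52), miR408 at -3.86 (SE 0.62) and miR393 at 3.97 (SE 0.64), and miR398b was 4.54-fold lower. As a sum of end variants miR393 stood at 3.49 (SE 0.57).

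The epidermis had the highest measured level of miR166 of the 4 seed coat subregions, 298764 ± 10374 CPM (n = 2) against 22543 (7.23, SE 0.47). The place of the hilum in this order is uncertain, since its low level may be a loss by first bases. In the development list miR164 also rose (1.91, SE 0.39, 179 against 109 CPM) and 14 members did not pass, while over the list alone 3 rose and 1 fell. In the nutrient list miR2119 (-2.59, SE 0.61), miR408 (-2.03, SE 0.51, 54.1 against 2961 CPM) and miR398b (-1.69, SE 0.46) fell, and in the nlr list miR482b (-2.24, SE 0.52) and miR2118 (-1.96, SE 0.43), with counts of 3 and 2 also over the list alone. In the legume list miR3522 fell (-1.46, SE 0.49), 1 also over the list alone, and the machinery list had 0 over all sequences in edgeR's test and 1 over the list alone. Outside the lists, TCGGACCAGGCTTCATTCC (6.74, SE 0.41) and TCGGACCAGGCTTCATTCCC (6.30, SE 0.45), shorter forms of miR166, were higher. TCTCGGACCAGGCTTCATTC, another end variant of miR166 (-5.19, SE 0.73, 1.80 against 456 CPM), and TATGGGGGGATTGGGAAGGAA (-3.17, SE 0.52) were lower. Changed by edgeR's test were 1507 sequences, 1196 higher and 311 lower.

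For the epidermis the split was 474 higher and 551 lower without TMM, and the median over all tested sequences was 0.30, and -0.21 without TMM. Without TMM 4 of the 6 members named by the rule moved down by over 1.5-fold. The count was 2414 with DESeq2, 406 without epidermis 2, 970 without outer integument 1, 2374 and 2424 without endosperm 1 and 2, and 626 without the inner integument libraries. Without the inner integument libraries, miR164 (0.81, SE 0.45), miR2119 (-1.73, SE 0.62), miR408 (0.31, SE 0.50), miR482b (-0.87, SE 0.52) and miR2118 (-1.34, SE 0.46) did not pass. Without the hilum libraries miR166 stood at 3.73 (SE 0.51), its 2 shorter forms at 4.44 (SE 0.45) and 3.42 (SE 0.43), and TCTCGGACCAGGCTTCATTC at -3.52 (SE 0.70). Without the hilum libraries miR408 (-4.45, SE 0.62), miR482b (-3.24, SE 0.58), miR2119 (-3.48, SE 0.69) and TATGGGGGGATTGGGAAGGAA (-4.16, SE 0.59) were further from 0, and TATGGGGGGATTGGGAAGGAA stood at -1.90 (SE 0.52) without the inner integument libraries. As a sum of end variants miR166 stood at 3.47 (SE 0.40). Calls were lost without epidermis 1 for miR482b (adjusted p = 0.0691) and miR408 (adjusted p = 0.0921), and without epidermis 2 for miR2119 (adjusted p = 0.161), miR482b (adjusted p = 0.0516), miR408 (adjusted p = 0.0787) and miR2118 (adjusted p = 0.0605). By fry the nutrient (adjusted p = 0.00513), machinery (adjusted p = 0.0488) and nlr lists (adjusted p = 0.0255) were lower. By camera, against the other sequences, adjusted p was 0.346, 0.471 and 0.471. All 3 fry calls were lost without the inner integument libraries (adjusted p = 0.664, 0.124 and 0.177) and at 1 CPM (adjusted p = 0.0647, 0.915 and 0.0508). The machinery call was lost in 12 of 16 fits that left out 1 library (all but either embryo proper, cotyledon 2 and outer integument 1, adjusted p 0.056 to 0.168), with 20 to 22 nt sequences (adjusted p = 0.11), without the hilum libraries (adjusted p = 0.107) and without the sequences depleted in the hilum (adjusted p = 0.0517), and the nlr call without epidermis 1, hilum 1, inner integument 2 or outer integument 2 (adjusted p 0.0514 to 0.292). The development (adjusted p = 0.134) and legume lists (adjusted p = 0.222) were not called, but the first was called higher without epidermis 1 (adjusted p = 0.0234) and with 20 to 22 nt sequences (adjusted p = 0.0129), and the second lower without epidermis 2 (adjusted p = 0.0172) and without TMM (adjusted p = 0.000669).

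In the inner integument the tested microRNAs of copper proteins rose and most tested development members fell. All 4 nutrient members rose, also over the list alone: miR408 (128-fold, SE 0.44 on the log2 scale, 8548 ± 460 CPM, n = 2, against 130), miR398b (5.47, SE 0.39, 2800 against 75.4 CPM), miR397 (3.50, SE 0.79, 3.46 against 0.331 CPM) and miR2119 (3.23, SE 0.47, 205 against 27.8 CPM). Of the nlr list miR482b (4.48, SE 0.41, 59059 ± 5876 CPM, n = 2, against 2820) and miR2118 (2.40, SE 0.35, 10709 against 2309 CPM) rose and 2 did not pass, as over the list alone. In the development list 10 members fell, 2 rose and 4 did not pass, as over the list alone. miR393 was at least 16.9-fold lower, and miR396a (-5.72, SE 0.88, 1.80 against 163 CPM) and miR164 (-3.51, SE 0.54, 14.8 against 164 CPM) fell. miR319b was at 0 against 0.944 CPM, a bound of at least 1.95-fold lower. The 2 that rose were miR156a (2.75, SE 0.44) and miR166 (2.87, SE 0.43), the latter at 44667 against 107241 CPM. The miR166 call rested on the hilum, since without its libraries miR166 stood at -1.24 (SE 0.55, adjusted p = 0.0633). In the machinery list miR168 rose (2.33, SE 0.38) and miR162 fell (-1.28, SE 0.54), and in the legume list miR3522 rose (2.57, SE 0.41) and miR1508 fell (-2.33, SE 0.53), each also over the list alone. The inner integument libraries were also those with 18.8% of 5S ribosomal RNA fragments and 31.2% of reads of 18 to 20 and 25 to 26 nt.

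Outside the lists, TGCACTGCCTCTTCCCTGGC, a shorter form of miR408 (7.10, SE 0.43, 1784 against 16.5 CPM), and GCTGGGAACAGGCAGGGCACG (7.82, SE 0.48, 549 against 5.96 CPM) were higher in the inner integument. TTGGCTGAGAACAACAAGGGT (-8.01, SE 0.74, 0.905 against 357 CPM) and TTTTGGACTGAAGGGAGCTCC, an end variant of miR319 (at least 450-fold lower, 0 against 356 CPM), were lower. By edgeR's test 6457 sequences changed, 3198 higher and 3259 lower (2581 and 4260 with DESeq2), and 79.1% of the lower ones were 24 nt long against 26.8% of the higher ones. The median over all tested sequences was -0.16, and -0.35 with DESeq2. By fry the nutrient (adjusted p = 4.87e-05), nlr (adjusted p = 0.00198) and machinery lists (adjusted p = 0.0488) were higher and the development list (adjusted p = 0.021) lower. By camera, against the other sequences, adjusted p was 0.346, 0.633, 0.69 and 0.664. The legume list was not called (adjusted p = 0.813), and was lower with 20 to 22 nt sequences (adjusted p = 0.00981). The development call was lost without inner integument 1 (adjusted p = 0.146) or 2 (adjusted p = 0.0714). The machinery call was lost in 13 of 16 fits that left out 1 library (all but either embryo proper and outer integument 2, adjusted p 0.0598 to 0.184), with 20 to 22 nt sequences (adjusted p = 0.529), at 1 CPM (adjusted p = 0.671), with summed end variants (adjusted p = 0.068), with the replicate number as a block (adjusted p = 0.0637), without the hilum libraries (adjusted p = 0.0579) and without the sequences depleted in the hilum (adjusted p = 0.0517). miR319b lost its call without hilum 2 (adjusted p = 1.0) or inner integument 1 (adjusted p = 0.114) or 2 (adjusted p = 0.107). Without the hilum libraries miR408 stood at 5.65 (SE 0.51) and miR398b at 4.68 (SE 0.47), and as a sum of end variants miR396a stood at -2.35 (SE 0.53) and miR393 at -3.42 (SE 0.82). With only 20 to 22 nt sequences miR408 stood at 6.39 (SE 0.41), miR398b at 4.85 (SE 0.36) and miR482b at 3.87 (SE 0.39). In that setting 4 of the 8 members named by the rule moved down by over 1.5-fold.

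In the outer integument few list members passed. In the development list 5 members rose and 11 did not pass, and over the list alone 6 rose and 1 fell. They were miR160 (4.07, SE 0.56, 20.4 against 2.37 CPM), miR319a (1.79, SE 0.52, 14.7 against 5.17 CPM), miR319b (at least 4.21-fold, 1.87 against 0.319 CPM), and miR166 (1.69, SE 0.44, 22933 against 114486 CPM) and miR396a (1.65, SE 0.56, 72.2 against 139 CPM), which had the lower mean CPM in the outer integument. The miR166 call rested on the hilum, and without its libraries miR166 was lower (-2.49, SE 0.60, adjusted p = 0.00674). In the legume list miR1508 (2.73, SE 0.40, 71.8 against 12.4 CPM) and miR1511 (1.34, SE 0.44) rose and 2 did not pass, as over the list alone. No nutrient, machinery or nlr member passed edgeR's test over all sequences or over the list alone. Outside the lists, TCTGAAGTGTTTGGGGGAACC, which holds bases 2 to 17 of the sulfate-responsive miR395, was at least 80.4-fold higher (185 against 5.59 CPM), and ATCCAACAATGACAGCGGCTGC was higher by 4.06 (SE 0.41). CTGTGTATTAGCTCTATCTGATCATT (-4.19, SE 0.56, 11.7 against 260 CPM) and GGAATGTTGTCTGGCTCGAGG (-2.77, SE 0.48, 154 against 1925 CPM) were lower.

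Between the outer integument and the other seed coat subregions, 1877 sequences passed edgeR's test, 1467 higher and 410 lower, around a median over all tested sequences of 0.28 (0.20 without TMM and 0.42 with DESeq2). The number was 3042 with DESeq2, 845 without outer integument 1, 391 without outer integument 2 and 1048 without the inner integument libraries. By fry the development (adjusted p = 0.0352) and legume lists (adjusted p = 0.00198) were higher. By camera, against the other sequences, adjusted p was 0.69 and 0.562. The nutrient (adjusted p = 0.17), machinery (adjusted p = 0.448) and nlr lists (adjusted p = 0.685) were not called, and the nutrient list was higher without the inner integument libraries (adjusted p = 0.00291). The development call was lost in 10 of 16 fits that left out 1 library (either axis, cotyledon, hilum or inner integument library, epidermis 1 or outer integument 2, adjusted p 0.0518 to 0.159), without the inner integument libraries (adjusted p = 0.458) and without the sequences depleted in the hilum (adjusted p = 0.0533). miR319a and miR319b lost their calls without outer integument 2 (adjusted p = 0.364 and 0.0902) and without the inner integument libraries (adjusted p = 0.207 and 0.0611). The sum of end variants stood at 3.60 (SE 0.40) for miR319a, and without the hilum libraries miR160 stood at 5.03 (SE 0.70). Without the inner integument libraries, where it was at 0, TCTGAAGTGTTTGGGGGAACC stood at 5.05 (SE 0.64).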

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

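The fits without the hilum libraries, without the inner integument libraries and without the starts depleted in the hilum were chosen after the results were seen, as were the subregion means for shares. Of 111 named calls, 90 passed in each of the 16 fits that left out 1 library, and 21 were lost in at least 1. With 1 library left, a subregion was assumed to vary like the others. No named member or sequence changed direction under another scaling (library totals or DESeq2). Lists under DESeq2, chalcone synthase small RNAs, 24-nt windows and shares without ribosomal, transfer and plastid RNA were not run. At 2 replicates the simulated 2-fold changes were mostly missed, so a microRNA that did not pass may still differ (for example miR171a at 1.37 with the embryo as axis and cotyledon only).

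In the order embryo and endosperm (each against seed coat, and endosperm against embryo between them), hilum, epidermis, inner and outer integument, the changed sequences numbered 2001, 2061, 2472, 785, 501, 1401 and 797 with only 20 to 22 nt sequences, where fewer were tested, and 32983, 64110, 52165, 4890, 7932, 46738 and 6489 at 1 CPM, where more were tested. Library totals gave 219 and DESeq2 307 for axis against cotyledon, and DESeq2 gave 2414 for the epidermis and 3042 for the outer integument. Without the inner integument libraries the hilum had 1308, the epidermis 626 and the outer integument 1048. Leaving out 1 library at a time gave 8 to 155 for axis against cotyledon, 824 to 3627 for the hilum, 406 to 2424 for the epidermis and 391 to 2781 for the outer integument. The cause was not tested in the cases other than the 2 filters.

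With camera, which compares a list with the other sequences as fry does not, 0 lists were called in each of the 8 comparisons. At 1 CPM, and also without the inner integument libraries, 1 list was called for the hilum and 0 for the epidermis, and without the starts depleted in the hilum 1 for the outer integument. Leaving out 1 library gave 1 to 3 called lists for axis against cotyledon, 1 to 2 for the hilum, 1 to 3 for the epidermis, 2 to 4 for the inner integument and 1 to 2 for the outer integument. Summed end variants reversed miR167a (-3.87) and the development list (adjusted p = 0.0137 by fry) in embryo against seed coat, and brought miR1511 there (-0.02) and miR167c in the hilum (-0.18) near 0. For miR167 the sum takes in the end variant named in endosperm against seed coat. That variant was at 1034 to 2125 CPM in the seed coat subregions and at 2.71 to 27.1 CPM in the embryo ones. The exact miR167a sequence had a mean of 12.6 CPM in the embryo. In the hilum the variant was at 1614 CPM, inside the range of the other seed coat subregions. Its levels thus go in the direction of both miR167 changes, and other end variants were not examined singly. The cause was not tested for miR1511 and the development list. Of the members named by the rule, 6 of 8 in the hilum, 6 of 6 in the epidermis and 2 of 4 in the outer integument moved by over 1.5-fold without the inner integument libraries, and 6 of 8 in the inner integument without the hilum libraries. For endosperm against seed coat 11 of 18 moved so without the inner integument libraries and 5 of 18 without the hilum libraries. With summed end variants 5 of 18 moved there, and 2 of 4 for axis against cotyledon. miR408 in the epidermis was at 0.31 without the inner integument libraries, which held most of it among the other subregions. The machinery list in the epidermis reversed at 1 CPM (adjusted p = 0.915 by fry, cause not tested). For the endosperm against the rest, the 21-nt share differed by 4.24 points among distinct sequences and 5.35 points without the 20 most abundant ones, and the 24-nt share by -15.02 and -21.42 points. Over subregion means these permutation tests gave p = 0.125, 0.125, 0.25 and 0.25. The inner integument, counted with the rest, was close to the endosperm among distinct sequences. The libraries of both held the fewest distinct sequences. For embryo against seed coat, the 21-nt share reversed to -2.02 points among distinct sequences and -2.46 points without the 20 most abundant ones. miR166 in the inner and outer integument, named beyond the rule, turned to -1.24 and -2.49 without the hilum libraries.

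With the replicate number as a block, the changed sequences numbered 5343 for embryo against seed coat, 8106 for endosperm against embryo, 8288 for endosperm against seed coat, 111 for axis against cotyledon, 2640 for the hilum, 1568 for the epidermis, 6440 for the inner and 1882 for the outer integument, each within 1.5 times the main count. Deviations of same-numbered libraries correlated at -0.13 to 0.15 over 28 pairs of subregions, over 0.1 in 5. Of 16 libraries, 10 correlated best with their own number. The 2 libraries of a subregion mirror each other around their mean, so these 16 are not separate observations. The numbers were not taken as a pairing. The block ended the calls of the nlr list in axis against cotyledon (adjusted p = 0.0545) and of the machinery list in the inner integument (adjusted p = 0.0637).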

Other observations

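The tests of library splits, of miR166 in the hilum, of library depth, of file layout and of RNA carried over from embryo or endosperm were chosen after the results were seen, and those of 5S fragments and of length make-up before. In both libraries of each embryo subregion and of the epidermis the most abundant sequence was miR166. In the other subregions the first place differed between the 2 libraries. It was held by the 26-nt 5S fragment (28313 CPM) and miR166 (18633 CPM) in endosperm 1 and 2, and by miR1507 (21722 CPM) and TCTCGGACCAGGCTTCATTCC (18514 CPM), an end variant of miR166, in hilum 1 and 2. In the inner integument it was the 26-nt 5S fragment (61268 CPM) and miR482b (63214 CPM). In the outer integument it was miR166 (33593 CPM) and GGAATGGGCTGATTGGGAAGC (51844 CPM), which is in none of the lists. The endosperm sequence CTTACAGAGAATGGAGCGCCT, at 5689 ± 2500 CPM there, was at 170 ± 30.5 CPM in the cotyledon, 27.9 ± 23.0 CPM in the inner integument and 1.74 ± 1.13 CPM in the hilum.

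Of the 35 splits of the 7 embryo and seed coat subregions, 1 gave as many changed sequences as the real one, the real one itself (5387), and the highest other was 5010, with hilum, inner and outer integument set against the rest. A fit of the 14 libraries in 2 groups gave 3647, and of its 35 splits that keep both libraries of a subregion together 1 gave as many, with 2474 as the highest other. The real split came first of 35 in both fits, the smallest share such a test can give. These splits were chosen after the results were seen, both fits use the same libraries, and 5010 is close to the real count. By their titles axis and cotyledon are parts of the embryo proper, so the 7 subregions may not be independent units. Chance is thus not excluded. Of 100 splits drawn over the 14 libraries, 1 gave as many as the real one and the highest other was 478, but most of these part the libraries of a subregion, so they decide nothing.

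The very low level of miR166 in both hilum libraries, under 35 CPM, may be a loss by first bases in these libraries. Distinct sequences that start TCGGAC and are not miR166 stood at 0.109 of the median of the other libraries in the higher hilum library. The form with 1 more T at its 5′ end was at 10433 CPM in the lower hilum library, inside the range of the other libraries, which argues against a low level in the tissue as the whole cause. A part of the drop from a lower level in the tissue stays open. Of the 31 depleted starts 29 had 3 or more G (93.5%, against 15.3% of those examined), and 0 starts were depleted in that way in any other subregion's libraries.

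Reads of 18 to 20 and 25 to 26 nt made up 25.2 to 33.5% of the endosperm and inner integument libraries, against 8.77 to 14.2% of the other 12. Depth alone is unlikely, since 2 libraries of other subregions with no more counts held at most 13.6%. Without the 5S fragments the 4 libraries still held at least 24.0%, above the highest of the others (13.2%), so these fragments are not the whole of it. The 4 are among the 6 libraries with another file layout, and the other two of these, embryo proper 1 and embryo axis 1, held at most 11.7%, below embryo proper 2 (12.6%), so that layout is not the whole cause either. The 4 also held the fewest distinct sequences, 296392 to 618380 per library, against at least 760856 in the others. The depth test used total counts and does not address this. A lower variety of sequences in these libraries, degraded RNA and a biological difference were not tested and stay open.

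The nutrient and nlr microRNAs that rose in the inner integument were tested against RNA carried over from embryo or endosperm. Of 6 called members, 4 (miR408, miR2119, miR482b and miR2118) were above their level in every embryo and endosperm subregion in both libraries. For miR398b, the share of RNA needed would bring at least 7.47 CPM of miR319a or miR319b, and for miR397 in its lower library at least 6.79 CPM, but these were at no more than 2.29 CPM and at 0. The length make-up of the libraries is not the whole cause either, since with 20 to 22 nt sequences the lowest log2 fold change of the 6 was 1.77. miR319a and miR319b were chosen as markers after the results were seen, and some other embryo sequences went the other way. miR156a and miR3522 were called higher in the inner integument. The end variant of miR3522 named above was at 29.3 CPM there, against 1.17 to 8.94 CPM in the other seed coat subregions. Carry-over in the source's proportions is thus not the whole cause for any of the 6. A part of it stays open for all 6, among them miR397 and miR398b, which were not above every source. A higher level in this tissue is a hypothesis found and tested on the same data.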
